A study of Mus musculus with 9 samples.

How the data were processed

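RNA was sequenced from gingiva of C57BL/6 mice in 9 libraries, 3 each from healthy, periodontitis and peri-implantitis sites, taken 2 weeks after ligation. Per the series' protocol, libraries were made with a TruSeq kit from 1 µg of RNA. The TPM values were made by the authors before the tables were deposited. Their processing notes name RSEM 1.3.3 and Bowtie2 2.4.1 and the builds mm39 and GRCm38.p6, without the role of each build. No annotation release, filter or scaling between libraries is stated. Each library has its own table of 55487 genes, with values to 2 decimals. A matrix of all libraries holds the same columns, except that healthy 1 and 2 carry each other's values, so 7 of 9 columns have the same number and 2 another. The separate tables were used.

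Totals per library were 981105.82 to 992586.01 TPM. No read counts are given, so depth and counting error are unknown, and no interval that needs them is given. No pair of libraries was identical. Symbols were found for 55141 gene identifiers, and the 346 without one held at most 0.085% of TPM in any library. Mitochondrial transcripts held 6.734% to 11.395%. Gene positions were taken from GENCODE M21 on GRCm38, which is not stated to be the authors' annotation.

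The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The plan put a count model first and named limma for files without counts, and that fallback was used. Genes with at least 1 TPM in at least 3 libraries were kept (15877). Log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a term for the group and all 9 libraries in a single fit (6 residual degrees of freedom, median prior degrees of freedom 3.92). The robust empirical Bayes step used a trend of variance on level. All p are two-sided and adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. Each p rests on 3 libraries per group, which are the replicates. By the series' design text the groups come from the same mice, but no label ties a library to a mouse. The main fit therefore treats all libraries as independent, and the replicate block is its alternative. The added 1 TPM makes fold changes of weakly expressed genes smaller than the ratio of their levels. Errors are SD of TPM or SE of log2 changes.

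The rule for named genes took, per contrast, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 TPM in the higher group, no overlap between libraries of the groups, and a symbol that is not a predicted gene or an immunoglobulin or T cell receptor segment. It also took up to 4 members of each called list and up to 2 of each other list, by adjusted p, and a panel of 23 genes in every contrast. Not every gene that the rule allows is printed. Of 41 fixed lists, 40 had at least 4 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and with fry as alternatives. Fry tests whether a list's genes move on balance in 1 direction, without comparing it with other genes. Ciliated, airway secretory and olfactory lists were added after the data were seen. The olfactory list was not called in any contrast (adjusted p = 0.904, 0.728 and 0.499).

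The overlap of the comparisons with healthy tissue was set against independent lists of the same sizes and against 100 simulated draws of unchanged groups compared with the same healthy libraries. To test the fit, values were drawn independently for each gene around a group mean with that gene's residual spread. Known shifts were added, in a single draw per comparison. On these simulated values the limma fit called 44%, 44% and 54% of genes raised by 1 on the log2 scale in the 3 comparisons. It called 88%, 90% and 86% of those raised by 2. False calls made up 4.29%, 8% and 4.73% of calls. Camera called 20 of 20 shifted lists and 0 of 800 unshifted ones. These were random sets of independently drawn genes, so the result does not give the false calls for lists whose genes move together.

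Alternatives were median-of-ratios and upper-quartile scaling, totals without genes over 1% of a library, an added 0.1 TPM, no filter, 1 TPM in 6 libraries, a fit to the groups compared alone, a replicate block, a minimum log2 change of 1, and each library left out in turn. Count models were planned as alternatives and were not run, for want of counts. Fits without the gland-rich healthy libraries, without immunoglobulin genes and with the matrix numbering as the block were added after the data were seen, as were upper-quartile scaling and totals without abundant genes for the lists. Near copies of single genes were sought with BLAST 2.17.0. Tables were handled in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.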

Results

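Transcript levels were measured by RNA sequencing in mouse gingiva, the soft tissue around the teeth, from C57BL/6 animals. The study set inflamed tissue around an implant beside inflamed tissue around a tooth of the same animals. It holds 3 groups of 3 libraries each, drawn from 3 mice according to the series' design text. Periodontitis libraries came from gingiva around the right upper first molar after a silk ligature was tied around the tooth, which lets plaque gather and starts inflammation. Peri-implantitis libraries came from gingiva around a ligatured titanium implant, 1 mm long and 0.5 mm wide, that stood in place of the left upper first molar. Tissue around the third molars, without a ligature, served as the healthy group. All tissue was taken 2 weeks after ligation. Tooth position therefore differs between the healthy group and both ligatured groups, and jaw side and surgery differ between the ligatured groups. Values were length-normalised transcript abundances scaled within each library (TPM), with column totals of 981105.82 to 992586.01. The files hold no read counts, so the sequencing depth is unknown. Between 14202 and 15624 genes per library reached 1 TPM.

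The groups separated. The first principal component of log2(TPM + 1) carried 58.73% of the variance and set the healthy libraries (scores of -104.52 to -61.14) apart from the ligatured ones (31.08 to 52.27). The second carried 12.36% and set periodontitis (26.54 to 34.37) apart from peri-implantitis (-58.77 to -15.63). Pearson correlations across genes were 0.972 to 0.974 between periodontitis libraries, 0.946 to 0.959 between peri-implantitis libraries and 0.927 to 0.945 between healthy libraries. They were 0.787 to 0.878 between healthy and periodontitis libraries, 0.776 to 0.893 between healthy and peri-implantitis libraries, and 0.924 to 0.956 between the ligatured groups. Genes are not independent replicates, so these values describe the libraries.

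**Figure D1:**
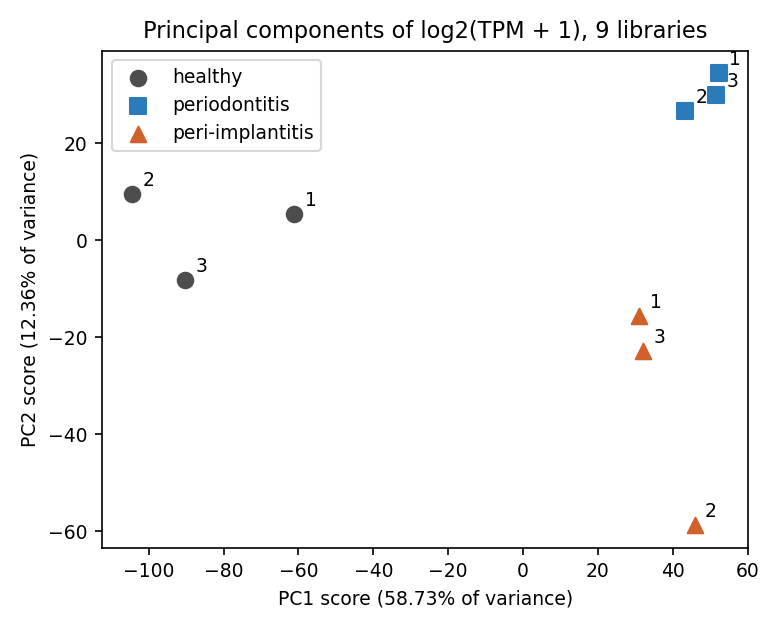
Scores of the 9 libraries on the first (58.73% of variance) and second (12.36%) principal components of log2(TPM + 1), 1 point per library, numbered by replicate, with colour and symbol for the group. Healthy libraries lie between -104.52 and -61.14 on the first component and all ligatured libraries above 31.

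The first comparison asks how gingiva around a ligatured tooth differs from healthy gingiva. The collagenase gene Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331) stood at 374 ± 126 TPM around ligatured teeth and 1.85 ± 0.637 TPM at healthy sites (mean ± SD, n = 3 per group), a log2 fold change of 7.01 ± 0.56 (SE) with an adjusted p of 0.000208. The acute-phase gene Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700) rose from 5.67 ± 0.761 to 980 ± 727 TPM, a log2 change of 6.95 ± 0.65. Col12a1 (ENSMUSG00000032332, chromosome 9, 79598991 to 79718831), a fibril-associated collagen, rose by 4.95 ± 0.41. The other largest rises under the naming rule were the casein gene Csn1s1 (4.51 ± 1.06), the beta-defensin gene Defb3 (4.49 ± 0.69), the calprotectin gene S100a8 (4.43 ± 0.53), the gelatinase gene Mmp9 (4.28 ± 0.37) and the fibrillar collagen gene Col11a1 (4.16 ± 0.39). Coordinates are those of GENCODE M21 on GRCm38, and all these genes are annotated as protein-coding where a position is given.

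Matrix, vessel and bone genes rose as groups. Of 22 tested genes for collagens and collagen processing, 18 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 4.53e-14). Among them Col1a1 rose by 3.76 ± 0.42, Col3a1 by 3.29 ± 0.29, Col6a3 by 3.02 ± 0.22 and the crosslinking enzyme gene Loxl2 by 2.94 ± 0.26 on the log2 scale. Of 20 proteases and protease inhibitors, 12 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 1.46e-08), among them the inhibitor gene Timp1 (3.59 ± 0.33). Of 16 genes of fibrosis, 13 rose (13 adjusted over the list alone; adjusted p = 1.13e-07), with Lrrc15 at 3.55 ± 0.27. Of 15 endothelial genes, 11 rose (11 adjusted over the list alone; adjusted p = 1.13e-07), led by Selp (3.41 ± 0.26) and Sele (3.34 ± 0.28), which encode selectins that capture leukocytes on the vessel wall, while the junction gene Cdh5 rose by 1.61 ± 0.14. With an estimated correlation these 4 lists were no longer called, each with an adjusted p of 0.214.

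Of 11 periodontal ligament and tendon genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.000884, and adjusted p = 0.22 with an estimated correlation). Postn rose by 2.56 ± 0.27 and Fmod by 3.75 ± 0.53, while Chad, a cartilage matrix gene, had a log2 change of -4.08 ± 0.47. Of 11 bone matrix genes, 6 rose (8 adjusted over the list alone; adjusted p = 0.00014, and adjusted p = 0.309 with an estimated correlation), among them Spp1 (3.28 ± 0.64), Ibsp (3.2 ± 0.68), Omd (2.44 ± 0.34) and the osteoblast regulator Runx2 (1.25 ± 0.26). Of 14 osteoclast genes, 6 rose (9 adjusted over the list alone; adjusted p = 0.000704, and adjusted p = 0.45 with an estimated correlation). The bone-resorbing protease gene Ctsk rose by 2.91 ± 0.33, Itgb3 by 1.56 ± 0.2 and Acp5 by 1.26 ± 0.33. Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, rose from 1.32 ± 0.443 to 6.29 ± 1.24 TPM (1.66 ± 0.28, adjusted p = 0.00309). Its decoy receptor gene Tnfrsf11b was at 4.55 ± 1.37 against 4.06 ± 3.43 TPM (adjusted p = 0.738). Of 15 basal and wound-edge epithelial genes, 5 rose (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.000884, and adjusted p = 0.345 with an estimated correlation), among them the wound keratins Krt16 (3.01 ± 0.38) and Krt6a (1.78 ± 0.31) and the basal keratin Krt14 (1.39 ± 0.29).

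Of 15 inflammatory cytokine genes, 3 rose (3 adjusted over the list alone), and the list was not called (adjusted p = 0.0929). S100a9 rose by 3.79 ± 0.56, and Il17a, the signature cytokine of Th17 cells, rose by 1.6 ± 0.49 at the edge of the threshold (adjusted p = 0.0491). Il6 was at 2.87 ± 0.849 against 0.09 ± 0.0819 TPM (adjusted p = 0.0787). Il1b, at 22.5 ± 12.9 against 16.1 ± 12.9 TPM (adjusted p = 0.635), did not pass the test, nor did Tnf, at 2.32 ± 1.39 against 4.88 ± 0.531 TPM (adjusted p = 0.167). Cxcl2 (adjusted p = 0.345), Arg1 (0.336), Mmp8 (0.613), the macrophage marker Adgre1 (0.46) and the suprabasal keratin Krt1 (0.555) did not pass either. The neutrophil list had 2 of 14 genes higher and 1 lower and the macrophage list 1 of 19 higher and 4 lower. Adjusted over the list alone these were 2 and 2, and 2 and 5, and neither list was called (adjusted p = 0.542 and 0.239). The monocyte gene Ly6c2 had a log2 change of -3.2 ± 0.26. Nos2 stayed below the expression filter, with 2.35 TPM as its highest value in any library.

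Lymphoid and antigen-presenting genes were lower around ligatured teeth. Of 20 B and plasma cell genes, 19 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 1.84e-14). The immunoglobulin light chain gene Igkc stood at 51.2 ± 41.2 against 10050 ± 4670 TPM, Jchain at 4.95 ± 4.54 against 677 ± 168 TPM, and the B cell receptor gene Cd79a at 0.61 ± 0.78 against 118 ± 69 TPM (log2 changes of -7.79 ± 0.59, -7.07 ± 0.51 and -6.07 ± 1.01). Immunoglobulin genes together held 0.0216% ± 0.0188 of TPM around ligatured teeth and 3.38% ± 1.29 at healthy sites. Of 19 T and NK cell genes, 16 fell (16 adjusted over the list alone; adjusted p = 6.56e-14), with Cd3g at -2.15 ± 0.22 and Cd3e at -2.03 ± 0.24. Of 13 genes of MHC class II antigen presentation, 11 fell (12 adjusted over the list alone; adjusted p = 6.71e-10), with H2-Aa at -2.3 ± 0.21 and H2-Eb1 at -2.09 ± 0.21. Of 20 interferon response genes, 18 fell (18 adjusted over the list alone; adjusted p = 1.73e-09), with Usp18 at -3.04 ± 0.46. With an estimated correlation each of these 4 lists had an adjusted p of 0.214. The healthy libraries that were high in lymphoid transcripts also held 864 to 46240 TPM of salivary gland transcripts, against 10.35 to 19.95 TPM around ligatured teeth. The complement gene C3 had a log2 change of -1.69 ± 0.2, although its list was not called (4 of 16 fell, 1 higher and 5 lower adjusted over the list alone, adjusted p = 0.179).

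The largest falls were in genes of salivary glands and secretory mucosa. Dcpp3 (ENSMUSG00000057417, chromosome 17, 23917458 to 23919441), a salivary secreted protein gene, stood at 15180 ± 20910 TPM at healthy sites and 0.65 ± 0.513 TPM around ligatured teeth, a log2 change of -11.69 ± 1.33. Reg3g (ENSMUSG00000030017, chromosome 6, 78466269 to 78468872), an antimicrobial lectin gene of mucosal epithelium, stood at 8948 ± 5320 against 2.11 ± 1.92 TPM (-11.5 ± 0.58). Sbpl (-10.14 ± 1.06), Dmbt1 (-9.71 ± 1.56), Wfdc18 (-9.64 ± 1.72) and the airway gene Bpifb1 (-9.14 ± 0.92) followed. Tff2, a mucosal trefoil peptide gene, and Dcpp1 were listed at 0 in all 3 periodontitis libraries, against 250.99 to 3902.85 TPM and 65.52 to 4210.38 TPM at healthy sites. The Dcpp genes form a family of close copies, so the split of reads among them is uncertain. Of 8 tested salivary gland genes, 7 fell (8 adjusted over the list alone; adjusted p = 7.21e-08, and adjusted p = 0.214 with an estimated correlation), with the immunoglobulin transporter gene Pigr at -6.8 ± 0.52. The summed level of all 18 matched genes of this list, tested or not, was 864, 46240 and 8186 TPM in the 3 healthy libraries. Around ligatured teeth it was 10.35 to 19.95 TPM. Lists of ciliated and airway secretory cell genes, added after the gland genes were seen, had 16 of 17 and 11 of 13 lower (16 and 12 adjusted over the list alone; camera adjusted p = 2.06e-17 and 3.79e-13, and adjusted p = 0.0719 for both with an estimated correlation). The simple-epithelium keratins Krt8 (-5.46 ± 0.54) and Krt18 (-5.12 ± 0.72) fell too.

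**Figure D2:**
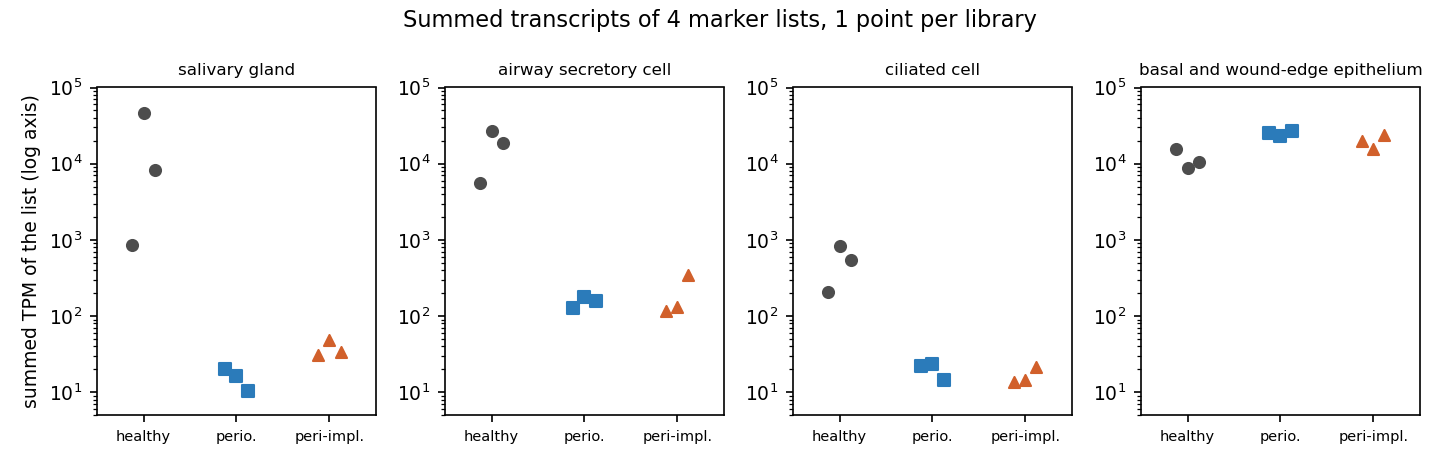
Summed TPM (log axis) of salivary gland, airway secretory, ciliated cell and basal epithelial genes, 1 point per library, by group. Salivary gland sums lie between 864 and 46240 TPM in healthy libraries and at 48.6 TPM or less in every ligatured library, while basal epithelial sums differ far less.

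In all, limma called 2975 of 15877 genes at an adjusted p under 0.05, 1286 higher and 1689 lower around ligatured teeth, and 522 and 1410 of them at 2-fold or more. The balance of directions depended on scaling: upper-quartile scaling called 2104 higher and 1725 lower, and totals without abundant genes 944 and 1818. The libraries of the groups did not overlap for 41.93% of genes, where chance gives 10%. The count was 1269 with healthy replicate 1 as the only healthy library, chosen after seeing the data as the one with the least gland transcript, and 1863 and 1976 without periodontitis replicates 1 and 2. Healthy replicate 1 still held 5541.79 TPM of airway secretory and 206.25 TPM of ciliated cell transcripts. The highest sums in ligatured libraries were 345.83 and 23.36 TPM. Fewer calls with that library alone can also come from the smaller healthy group. Of 56 called genes named for this comparison, 52 kept the call whichever single library was left out. Csn1s1 lost it without healthy replicate 1, 2 or 3 or periodontitis replicate 2 or 3 (adjusted p up to 0.0793), Acp5 without healthy replicate 2 or 3 or periodontitis replicate 1 or 2 (up to 0.105), and Ibsp without periodontitis replicate 2 (0.0524). Il17a lost it without any 1 of healthy replicates 1, 2 and 3, periodontitis replicates 2 and 3 and peri-implantitis replicates 1 and 3 (up to 0.159). Il6 passed without peri-implantitis replicate 2 or 3 (adjusted p = 0.00213 and 0.0397), with an added 0.1 TPM (0.00598) and in a fit of the 2 groups alone (0.00359). Camera called 21 of 40 lists with its preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.214 and fry called 20.

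The second comparison asks how gingiva around a ligatured implant differs from healthy gingiva. Saa3 rose to 3611 ± 3100 TPM, a log2 change of 8.76 ± 0.65 (adjusted p = 0.000176), and Mmp13 to 771 ± 686 TPM (7.75 ± 0.56, adjusted p = 0.000144). S100a8 rose from 90.7 ± 54.5 to 4941 ± 1495 TPM (5.9 ± 0.53) and its partner S100a9 from 146 ± 74.6 to 5320 ± 379 TPM (5.34 ± 0.56). The other largest rises under the naming rule were Col12a1 (5.97 ± 0.41), Csn1s1 (5.42 ± 1.06), the bone and macrophage glycoprotein gene Spp1 (5.3 ± 0.64) and Col11a1 (5.25 ± 0.39). Of 14 neutrophil genes, 12 rose (12 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.93e-06, and adjusted p = 0.335 with an estimated correlation), among them Clec4e (3.22 ± 0.45), the G-CSF receptor gene Csf3r (2.89 ± 0.43) and the collagenase gene Mmp8 (1.23 ± 0.28).

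Of 15 inflammatory cytokine genes, 7 rose (9 adjusted over the list alone; adjusted p = 8.82e-05, and adjusted p = 0.335 with an estimated correlation). Il1b rose from 16.1 ± 12.9 to 141 ± 69.2 TPM (3.18 ± 0.71, adjusted p = 0.02), Osm by 2.29 ± 0.42, Il6 by 2.47 ± 0.63 (adjusted p = 0.0248), Tnfsf11 by 2.34 ± 0.28 and Il17a by 1.79 ± 0.49 (adjusted p = 0.0309). Tnf was at 8.43 ± 4.98 against 4.88 ± 0.531 TPM (adjusted p = 0.439). Among chemokines, Cxcl2, which attracts neutrophils, rose by 4.7 ± 1.05 and Ccl4 by 3.47 ± 0.43, with 8 of 24 higher and 2 lower (10 and 5 adjusted over the list alone) and the list not called (adjusted p = 0.0688). Of 19 macrophage genes, 6 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.00428, and adjusted p = 0.544 with an estimated correlation). The lipid-handling macrophage genes Trem2 (2.82 ± 0.51) and Gpnmb (2.37 ± 0.33) and the marker gene Adgre1 (1.19 ± 0.33) rose, and Ly6c2 had a log2 change of -2.12 ± 0.26. Of 16 complement genes, 7 rose and 1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0305, and adjusted p = 0.598 with an estimated correlation), with C5ar1 at 2.41 ± 0.35, C1s1 at 1.21 ± 0.16 and Cfb at -1.86 ± 0.34. Fry did not call the complement list (adjusted p = 0.0579). The sensor gene Tlr2 rose by 1.69 ± 0.25. Arg1 stood at 371 ± 182 against 53.3 ± 63 TPM and narrowly missed the threshold (adjusted p = 0.0561).

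Of 22 collagen genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 5.15e-16, and adjusted p = 0.294 with an estimated correlation), with Col1a1 at 4.72 ± 0.42, Col3a1 at 3.9 ± 0.29 and Col5a2 at 3.63 ± 0.27. Of 20 proteases and inhibitors, 16 rose (18 adjusted over the list alone; adjusted p = 1.08e-12, and adjusted p = 0.286 with an estimated correlation), with Timp1 at 4.89 ± 0.33, Mmp9 at 4.26 ± 0.37 and the aggrecanase gene Adamts4 at 2.96 ± 0.25. Of 16 fibrosis genes, 13 rose (14 adjusted over the list alone; adjusted p = 1.43e-09, and adjusted p = 0.286 with an estimated correlation), with Lrrc15 at 4.13 ± 0.27 and Postn at 3.14 ± 0.27. Of 15 endothelial genes, 10 rose (11 adjusted over the list alone; adjusted p = 6.7e-07, and adjusted p = 0.294 with an estimated correlation), with Selp at 3.65 ± 0.26 and Cdh5 at 1.67 ± 0.14. Of 14 osteoclast genes, 8 rose (10 adjusted over the list alone; adjusted p = 6.15e-06, and adjusted p = 0.335 with an estimated correlation), with Ctsk at 3.56 ± 0.33 and Acp5 at 1.51 ± 0.33. Of 11 bone matrix genes, 7 rose (9 adjusted over the list alone; adjusted p = 1.14e-05, and adjusted p = 0.294 with an estimated correlation), with Alpl at 3.76 ± 0.64, Omd at 2.6 ± 0.34 and Runx2 at 1.72 ± 0.26. Periodontal ligament and tendon genes had a median log2 change of 1.37, close to the 1.48 around teeth. Limma called 6 of these 11 genes higher and 1 lower (8 and 1 adjusted over the list alone). Camera called the list higher (adjusted p = 0.00114, and adjusted p = 0.294 with an estimated correlation). Tnfrsf11b was at 7.19 ± 5.38 against 4.06 ± 3.43 TPM (adjusted p = 0.494). Of 17 hypoxia response genes, 8 rose (8 adjusted over the list alone; adjusted p = 0.00529, and adjusted p = 0.432 with an estimated correlation), with Hif1a at 1.97 ± 0.3 and the glucose transporter gene Slc2a1 at 1.54 ± 0.17. Of 18 oxidative stress and metal-handling genes, 5 rose (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.286 with an estimated correlation), with the haem oxygenase gene Hmox1 at 2.62 ± 0.43 and the zinc transporter gene Slc39a14 at 2.09 ± 0.24. In the epithelium Krt6b (3.26 ± 0.64) and Krt16 (2.82 ± 0.38) rose and Krt15 had a log2 change of -2.4 ± 0.46. Krt14 (0.83 ± 0.29, adjusted p = 0.0737) and Krt1 (-1.36 ± 0.44, adjusted p = 0.0592) did not pass the test.

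Lymphoid and glandular genes were lower here too. Of 20 B and plasma cell genes, 14 fell and 1 rose (19 and 1 adjusted over the list alone; adjusted p = 1.43e-09, and adjusted p = 0.294 with an estimated correlation), with Jchain at -3.64 ± 0.51 and Igkc at -3.4 ± 0.59, while Cd79a, at 13.6 ± 11.5 against 118 ± 69 TPM, missed the threshold (adjusted p = 0.0565). Of 19 T and NK cell genes, 12 fell (14 adjusted over the list alone; adjusted p = 8.3e-08, and adjusted p = 0.294 with an estimated correlation), with Cd3e at -1.24 ± 0.24. Of 13 MHC class II genes, 10 fell and 1 rose (10 and 2 adjusted over the list alone; adjusted p = 3.7e-05, and adjusted p = 0.335 with an estimated correlation), with H2-Aa at -1.46 ± 0.21. Of 20 interferon response genes, 7 fell (10 adjusted over the list alone; adjusted p = 2.32e-06, and adjusted p = 0.335 with an estimated correlation), with Usp18 at -2.8 ± 0.46. The 8 largest falls named the genes seen around teeth: Dcpp3 (-11.84 ± 1.33), Reg3g (-10.58 ± 0.58), Sbpl (-10.14 ± 1.06), Tff2 (-9.87 ± 0.86), Dmbt1 (-9.79 ± 1.56), Wfdc18 (-9.32 ± 1.72), Bpifb1 (-9.3 ± 0.92) and Dcpp1 (-8.83 ± 1.31). The summed salivary gland level at implants was 30.6 to 48.64 TPM, against 864 to 46240 TPM at the healthy sites where lymphoid transcripts were high as well. Of the added ciliated and airway secretory genes, 16 of 17 and 11 of 13 fell (17 and 13 adjusted over the list alone; adjusted p = 6.59e-19 and 1.72e-15, and adjusted p = 0.0619 for both with an estimated correlation).

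In all, 3002 genes were called, 1547 higher and 1455 lower at implants, with 791 and 1156 at 2-fold or more and 32.08% of genes without overlap between the groups' libraries, where chance gives 10%. Here too the balance turned with scaling, to 1369 higher and 1727 lower with median-of-ratios scaling and 1307 and 1570 with totals without abundant genes. The count was 1385 with healthy replicate 1 as the only healthy library, and the interferon response list then lost its call (adjusted p = 0.0689). Of 63 called genes named here, 58 kept the call whichever single library was left out. Il1b and Cxcl2 lost it without healthy replicate 1 or 2 or peri-implantitis replicate 2 or 3 (adjusted p up to 0.0693 and 0.0766), Il6 without healthy replicate 1, 2 or 3 (up to 0.0784), and Il17a without any 1 of those 3 or peri-implantitis replicate 2 or 3 (up to 0.107). Adgre1 lost it without healthy replicate 1, periodontitis replicate 2 or peri-implantitis replicate 1, 2 or 3 (up to 0.114). Cd79a passed without peri-implantitis replicate 3 (adjusted p = 0.0358), Arg1 without healthy replicate 3 (0.0135), Krt1 without peri-implantitis replicate 1 (0.0143) and Krt14 without healthy replicate 1 (0.00462). With median-of-ratios and upper-quartile scaling Cd79a (0.0352 and 0.0395) and Arg1 (0.0487 and 0.0449) passed as well, and Krt1 did with abundant genes left out of the totals (0.0484). The macrophage list lost its call without healthy replicate 1 (0.0529) and the complement list without healthy replicate 1 (0.125) or peri-implantitis replicate 2 (0.097). Camera called 23 of 40 lists, and 0 with an estimated correlation (lowest adjusted p of 0.286, with 22 called by fry).

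**Figure D3:**
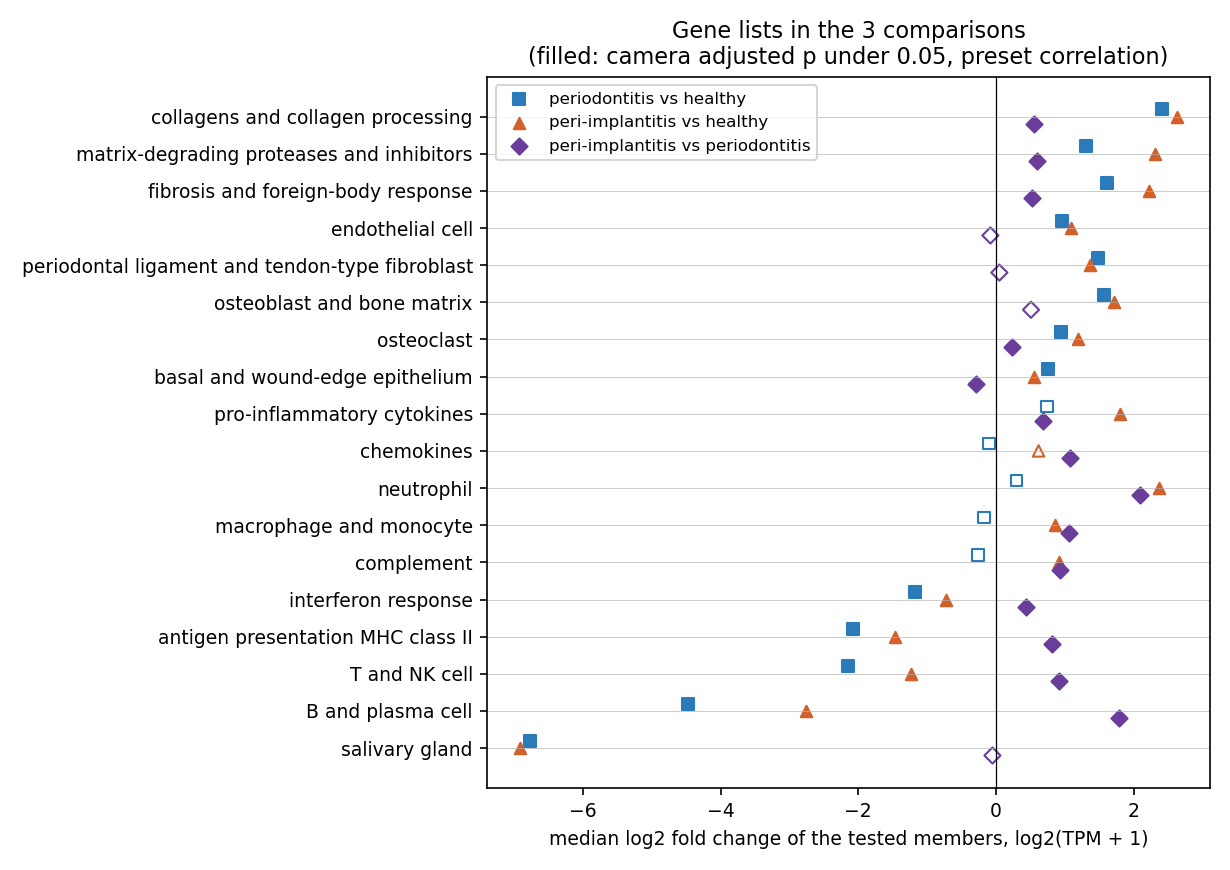
Median log2 fold change of the tested genes of 18 lists (horizontal axis) in the 3 comparisons, with filled symbols for lists called by camera with its preset correlation. Neutrophil genes have medians of 0.3 around teeth and 2.37 around implants against healthy tissue, and T and NK cell genes -2.15 and -1.24.

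The changes around teeth and around implants ran largely in parallel. Of the called genes, 881 were higher in both and 1195 lower in both, where independent lists of the same sizes would share 125.3 and 154.8. These shared calls were 69.8% of those around teeth and 69.2% of those around implants. Simulated unchanged groups against the same healthy libraries shared a median of 0. Such groups hold no true change, so few calls arise for them to share. This 0 therefore does not show what the shared healthy libraries add where genes do change. Log2 fold changes correlated across genes with r = 0.876, against a simulated median of 0.616 and a highest simulated value of 0.649 over 100 draws. Their covariance was 0.959, against a simulated 0.078. The simulated genes varied independently of each other, so the simulated values scatter less than those of genes that move together would. The difference in covariance estimates all that the ligatured groups share against the healthy libraries. That takes in gland transcripts and tooth position, so it does not estimate the ligature effect alone. Both comparisons use the same 3 healthy libraries, which cannot be split into 2 sets of at least 2 libraries, so part of the excess of shared calls may come from them. Called in opposite directions were 2 genes, Mcemp1, named outside the rule after its values were seen, and Clec7a. Mcemp1 (ENSMUSG00000013974, chromosome 8, 3665754 to 3669259), a mast cell and myeloid membrane protein gene, changed by -0.87 ± 0.25 around teeth and 1.07 ± 0.25 around implants. Clec7a (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779), which encodes the fungal beta-glucan receptor dectin-1 and is annotated as a polymorphic pseudogene, changed by -1.54 ± 0.3 and 1.24 ± 0.3.

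**Figure D4:**
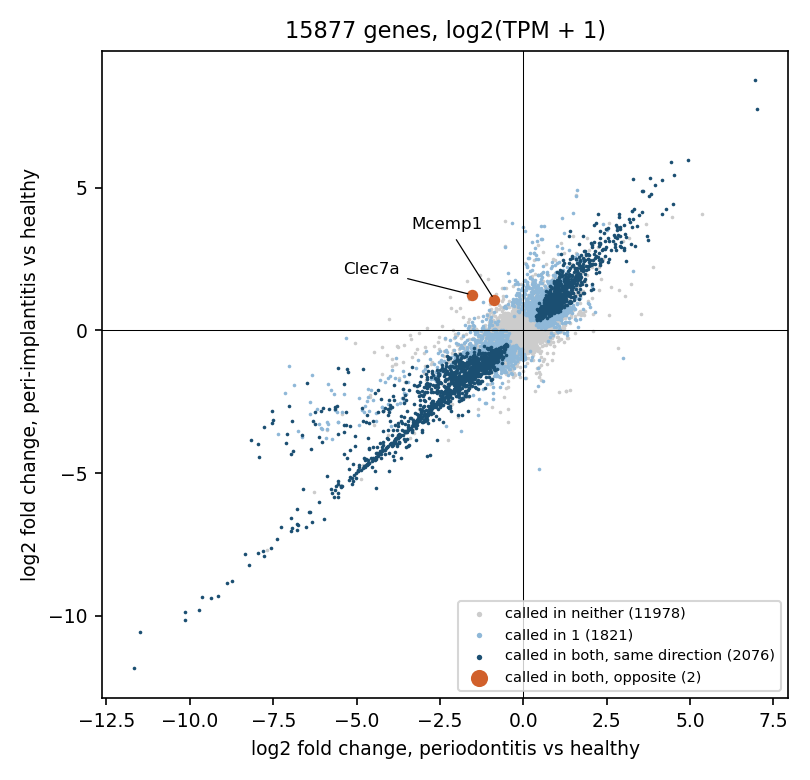
Log2 fold change against healthy tissue around teeth (horizontal) and around implants (vertical) for 15877 genes, coloured by where each was called. Called in both were 2076 genes with the same direction and 2 with opposite directions.

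The third comparison sets implant against tooth directly. The chemokine genes Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) and Ccl4 stood at 37.9 ± 24.8 against 0.957 ± 0.829 TPM and at 31.4 ± 17.4 against 1.72 ± 0.789 TPM, log2 changes of 4.1 ± 0.63 (adjusted p = 0.0373) and 3.42 ± 0.43 (adjusted p = 0.0187). Acod1, the itaconate-producing enzyme gene of activated macrophages, rose by 3.49 ± 0.49, Jchain by 3.43 ± 0.51 and the macrophage elastase gene Mmp12 by 3.02 ± 0.46. The receptor genes Lilr4b (2.84 ± 0.46), Clec7a (2.78 ± 0.3, adjusted p = 0.0077) and Clec4d (2.77 ± 0.37) completed the 8 largest rises. In all 91 genes were called, 88 of them higher at implants, 84 by 2-fold or more, and 18 of the 88 were immunoglobulin genes, among them Igkc (4.39 ± 0.59). Immunoglobulin genes together held 0.384% ± 0.0389 of TPM at implants and 0.0216% ± 0.0188 at teeth, both under the 3.38% ± 1.29 of healthy sites. Of the 88 genes, 36 were called higher than healthy at implants and 1 at teeth, while 54 were called lower than healthy at teeth and 26 at implants.

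All 3 genes that were lower at implants can be named. Pcp4, which encodes a calmodulin-binding peptide, stood at 3.79 ± 1.4 against 12.2 ± 1.77 TPM (-1.5 ± 0.24, adjusted p = 0.0322), and Nme3, a nucleoside diphosphate kinase gene, at 23.6 ± 3.76 against 45.6 ± 5.41 TPM (-0.93 ± 0.16, adjusted p = 0.0429). The third, Gm15516 (ENSMUSG00000082662, chromosome 14, 45713132 to 45713324), named outside the rule after its values were seen, is annotated as a processed pseudogene. It was listed at 0 in all 3 peri-implantitis libraries and at 32.72 to 48.36 TPM around teeth. Its 193-base transcript is 99.482% identical to Rpl9, so its value is uncertain.

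Whole lists of leukocyte genes leaned towards the implant, although few of their genes passed the test singly. Neutrophil genes had a median log2 change of 2.09, with 3 of 14 called higher (13 adjusted over the list alone; camera adjusted p = 2.27e-14, and adjusted p = 0.183 with an estimated correlation). These 3 were Clec4e (2.68 ± 0.45), Csf3r (2.54 ± 0.43) and the decoy receptor gene Il1r2 (1.78 ± 0.26). Macrophage genes had a median of 1.06, with 0 of 19 called and 17 adjusted over the list alone (adjusted p = 5.55e-13, and adjusted p = 0.183 with an estimated correlation), as for Apoe (0.95 ± 0.22, adjusted p = 0.103). B and plasma cell genes had a median of 1.79, with 2 of 20 called (7 adjusted over the list alone; adjusted p = 1.26e-11, and adjusted p = 0.19 with an estimated correlation). T and NK cell genes had a median of 0.91, with 0 of 19 called and 13 adjusted over the list alone (adjusted p = 1.76e-09, and adjusted p = 0.195 with an estimated correlation), as for Ctla4 (1.35 ± 0.27, adjusted p = 0.0663, and 0.0434 with a filter of 1 TPM in 6 libraries). Chemokine genes had a median of 1.08, with 3 of 24 called (5 adjusted over the list alone; adjusted p = 1.32e-07, and adjusted p = 0.161 with an estimated correlation), among them the interferon-induced Cxcl9 (1.79 ± 0.31). Complement genes had a median of 0.93, with 2 of 16 called (11 adjusted over the list alone; adjusted p = 1.26e-11, and adjusted p = 0.19 with an estimated correlation), namely C3 (1.34 ± 0.2) and the integrin gene Itgb2 (1.61 ± 0.25). MHC class II genes had a median of 0.82, with 0 of 13 called and 9 adjusted over the list alone (adjusted p = 4.9e-09, and adjusted p = 0.19 with an estimated correlation), as for Ctss (1.72 ± 0.32, adjusted p = 0.064, and 0.0482 with that filter). The endosomal sensor gene Tlr13 (1.45 ± 0.25) and the dendritic cell integrin gene Itgax (1.3 ± 0.22) were called higher.

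**Figure D5:**
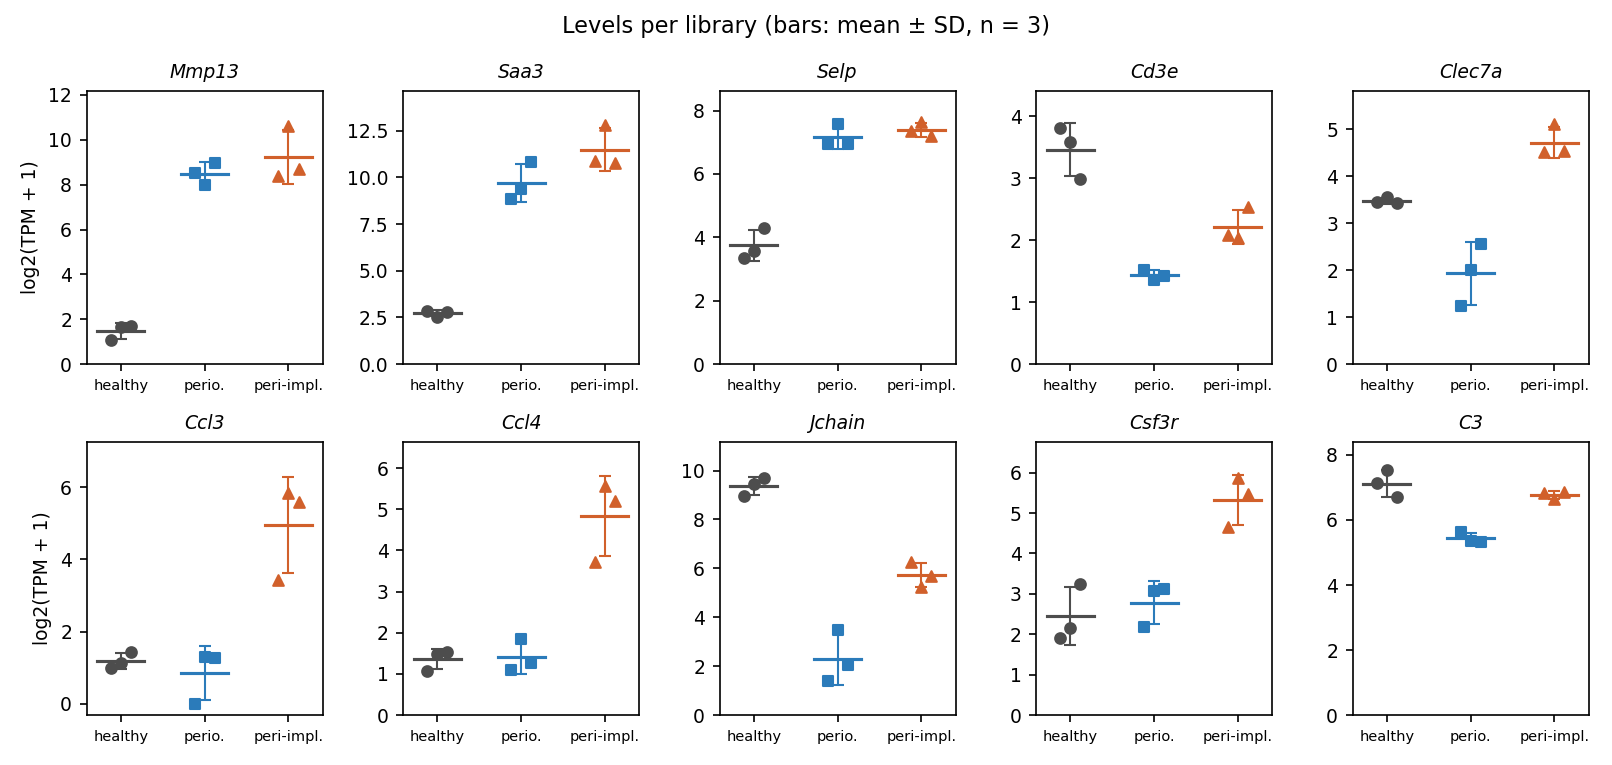
Log2(TPM + 1) of 10 genes, 1 point per library, with the mean and SD of each group (n = 3). Clec7a lies lower at teeth and higher at implants than in healthy tissue, and Ccl3 and Ccl4 are highest in the peri-implantitis libraries.

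Of 20 proteases and inhibitors, 1 was called higher at implants, Mmp12 (5 adjusted over the list alone; camera adjusted p = 3.03e-05, and adjusted p = 0.313 with an estimated correlation). Of 22 collagen, 16 fibrosis and 14 osteoclast genes, 0 were called and 0 adjusted over the list alone. Camera called these 3 lists higher at implants (adjusted p = 0.000233, 0.00443 and 0.0259, and adjusted p = 0.454, 0.414 and 0.555 with an estimated correlation). The osteoclast list lost its call without periodontitis replicate 3 (0.114) or peri-implantitis replicate 2 (0.853), and the fibrosis list without peri-implantitis replicate 2 (0.0761). Fry called none of the 4 lists (adjusted p = 0.123, 0.263, 0.204 and 0.384).

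Col1a1 stood at 2724 ± 1300 TPM at implants against 1377 ± 573 TPM at teeth (adjusted p = 0.425), Col3a1 at 2642 ± 750 against 1770 ± 705 (0.457), Mmp13 at 771 ± 686 against 374 ± 126 (0.673) and Mmp9 at 92.6 ± 54.9 against 87.3 ± 25 (0.998). Ctsk stood at 401 ± 194 against 248 ± 88.3 TPM (0.504), Acp5 at 166 ± 89.8 against 130 ± 32.5 (0.841), Tnfsf11 at 11.2 ± 4.88 against 6.29 ± 1.24 (0.392) and Tnfrsf11b at 7.19 ± 5.38 against 4.55 ± 1.37 (0.886). Of 15 inflammatory cytokine genes, 0 were called and 3 were higher adjusted over the list alone. Camera called the list higher (adjusted p = 0.000147, and adjusted p = 0.289 with an estimated correlation), and fry did not call it (adjusted p = 0.123). The inflammatory genes Il1b (2.62 ± 0.71, adjusted p = 0.214), Tnf (1.44 ± 0.42, 0.208), Il6 (0.66 ± 0.63, 0.743), Il17a (0.2 ± 0.49, 0.932), Cxcl2 (3.11 ± 1.05, 0.329), S100a8 (1.46 ± 0.53, 0.348), S100a9 (1.55 ± 0.56, 0.348), Mmp8 (1 ± 0.28, 0.187) and Arg1 (1.81 ± 0.97, 0.541) did not pass, nor did Cd79a (2.66 ± 1.01, 0.378), Cd3e (0.79 ± 0.24, 0.237) and Adgre1 (0.8 ± 0.33, 0.403). Krt14 (-0.56 ± 0.29, 0.507) and Krt1 (-0.94 ± 0.44, 0.454) did not pass either. The list medians were -0.08 for endothelial, 0.07 for fibroblast and 0.05 for periodontal ligament genes, and camera called none of these 3 lists (adjusted p = 0.413, 0.708 and 0.741). Their fry adjusted p were 0.794, 0.794 and 0.989, and limma called 0 of their genes.

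The count of 91 rested on single libraries and on scaling. It was 9, 19 and 11 without periodontitis replicates 1, 2 and 3, 153, 38 and 23 without peri-implantitis replicates 1, 2 and 3, and 32 and 164 without healthy replicates 2 and 3, while median-of-ratios scaling gave 54, upper-quartile scaling 49 and no expression filter 20. Of 22 called genes named for this comparison, 19 lost the call without at least 1 library, as Ccl3 did without 7 of the 9 (adjusted p of 0.00227 to 0.131), while Clec7a kept it in all 9 fits (0.00485 to 0.0363). An unadjusted p under 0.05 was reached by 1848 genes. The groups' libraries did not overlap for 18.11% of genes, where chance gives 10%. Camera called 26 of 40 lists, fry 12, and camera with an estimated correlation 0 (lowest adjusted p of 0.161).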

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

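The tests that weigh explanations of the gland, leukocyte and lymphocyte patterns were chosen only after the result was seen, while limma's comparisons, the fits without single libraries and the splits of the libraries were planned. The change from healthy tissue differed between implant and tooth sites for 91 genes, by limma's test of the difference itself. For Mcemp1 the difference of the log2 changes was 1.94 ± 0.25 (adjusted p = 0.0187) and for Clec7a 2.78 ± 0.3 (adjusted p = 0.0077), with changes from healthy in opposite directions for both genes. All 3 peri-implantitis libraries lay above all 3 periodontitis libraries for both genes. Both were picked for calls in opposite directions against healthy tissue, so this order adds no separate evidence. The call of Mcemp1 was lost without periodontitis replicate 1, 2 or 3 or peri-implantitis replicate 3 (adjusted p up to 0.081).

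Gland, ciliated and airway secretory transcripts were high at healthy sites. The tables argue against per-million scaling as the whole cause. With abundant genes left out of the totals, the scaling factors of the libraries lay between 0.958 and 1.038. The gland, ciliated and airway lists had far larger median log2 changes around teeth, -6.77, -3.76 and -6.26. Factors so alike leave little room to lose a call, and 32 of the 32 members called lower around teeth (36 tested) stayed called. Tissue from outside the gingiva is a candidate source: the salivary gland sum differed 53.5-fold between healthy libraries and the basal epithelial sum 1.77-fold, a ratio of 30.2, with Dcpp3 and Wfdc18 among the most abundant genes of a healthy library. Of the lists' matched members, 3 of 18 gland, 5 of 20 ciliated and 7 of 16 airway genes exceeded 1 TPM in a ligatured library, and 2 airway genes are also in the gland list. Third-molar against first-molar position cannot be told apart from the ligature, since both ligatured groups come from the first molar and their median difference over these genes was -0.007.

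Leukocyte lists leaned towards the implant over the tooth, with a positive log2 change in 71 of 72 members. Limma called 3 of 14 neutrophil, 0 of 19 macrophage, 2 of 20 B and plasma cell and 0 of 19 T and NK cell genes. A lower share of epithelium alone would raise stromal and vascular members alike. The leukocyte mean less the mean of 50 stromal and vascular members was higher at implants by 1.52 on the log2 scale (pooled SD 0.35). This argues against a lower share of epithelium as the whole cause. Epithelial genes were not part of this test, so a part played by it stays open. The tables argue against a single library, since 3 of 3 peri-implantitis libraries lay above every periodontitis library. They also argue against scaling, since the median change was 1.25 with median-of-ratios scaling and 1.28 without. A difference between implant and tooth lesions stays open as a hypothesis, as do jaw side, tooth extraction and implant surgery, which go with the implant in every library and were not tested.

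Lymphocyte and MHC class II transcripts were lower at ligatured than at healthy sites. Dilution by matrix and epithelial RNA alone would lower all leukocyte transcripts alike. The mean of 52 lymphoid and MHC class II members less that of 33 neutrophil and macrophage members was compared with healthy sites. Around teeth it differed by -2.85 (pooled SD 0.64), which argues against dilution as the whole cause there. A gain of myeloid transcripts beside dilution would lower this difference too, so a part played by dilution stays open. Implant sites were not tested in this way. Lymphoid cells brought in with gland or airway tissue cannot be told apart from a loss at the lesions with 3 healthy libraries. The T and NK cell sum of the healthy library with the lowest gland sum was 1.55 times the mean of the others, while its B and plasma cell sum was the lowest of the 3 (8768 against 13175 and 18479 TPM). A response to the ligature and tooth position also stay open, untested.

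The 10 splits of 6 libraries are too few for a share under 0.05. The real split called 2975, 3002 and 91 genes around teeth, around implants and between them, and in each case 1 split of the 10 reached the real count, while the highest other split called 2, 2 and 3.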

How the results depend on the processing

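The fits without gland-rich healthy libraries, without immunoglobulin genes and with the matrix numbering, and the upper-quartile and abundant-gene scaling of lists, were chosen only after the data were seen. With healthy replicate 1 as the only healthy library, assumed to vary like the other groups, 1269 genes were called around teeth, 1385 around implants and 962 in both. That library still held airway secretory and ciliated transcripts, and the healthy group was smaller. The fit therefore does not show the effect of removing outside tissue. With all libraries, a minimum fold of 2 gave 1932 genes around teeth and 1947 around implants. Between implant and tooth, median-of-ratios scaling gave 54 genes, upper-quartile scaling 49 and no filter 20. An estimated inter-gene correlation left 0, 0 and 0 lists around teeth, around implants and between them, and fry called 12 between them. Leaving out single libraries gave 1863 to 3240 genes around teeth, 2119 to 2994 around implants, 9 to 164 between them and 1449 to 2239 in both. The correlation of fold changes was 0.825 to 0.897 over all alternatives. Every gene called in the 3 comparisons kept its sign in every alternative that tested it. Of the called genes, 2972 of 2975 around teeth, 2966 of 3002 around implants and 91 of 91 between them had no overlap between the groups' libraries. Leaving libraries out could not turn the sign of those genes.

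The numbers were not shown to pair the libraries by mouse: deviations from the group mean correlated at -0.146 to 0.095 in 9 pairs of equal number. With a replicate block 2587, 2526 and 96 genes were called, 1787 in both ligatured groups, and with the matrix numbering as the block 2462, 2496 and 51. Of named genes that had missed the threshold, the replicate block called Il1b (adjusted p = 0.00421), Ctss (0.0158) and Wif1 (0.0342) between implant and tooth, and Arg1 (0.0059) and Krt1 (0.0159) around implants. The matrix numbering called Ctss (0.0364), Arg1 (0.0306) and Il6 around teeth (0.0499). The cause of these shifts was not tested.

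Of 187 results for named genes, 141 were called. Of these, 44 lost the call in at least 1 alternative that kept the planned libraries or removed the gland-rich ones, and 28 when 1 library was left out, with 0 changes of sign. Changes of sign arose in 6 results that were not called. Leaving out single libraries moved Tnfrsf11b from -0.21 to 0.88 around teeth. Between implant and tooth it moved Il6 from -0.2 to 1.26, Il17a from -0.39 to 0.62, Tnfrsf11b from -0.14 to 0.88, Acp5 from -0.16 to 0.48 and Mmp9 from -0.47 to 0.24. Mmp9 was at 0.01 with abundant genes left out of the totals. The cause was not tested. The files give no depth, so its limits are unknown.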

Other observations

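The fits below follow the plan, while the genes listed at 0 in whole groups were picked only after their values were seen. The list of Wnt and BMP signalling genes was not called against healthy tissue (adjusted p = 0.132 around teeth and 0.558 around implants). Around teeth 6 of 19 rose and 1 fell (6 and 2 adjusted over the list alone), with Wnt5a, a non-canonical Wnt ligand gene, at 2.48 ± 0.26 and Bmp2 at 1.31 ± 0.19. Around implants 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Wnt5a at 2.91 ± 0.26 and the BMP antagonist gene Grem1 at 4.09 ± 0.4. Between implant and tooth, the Wnt inhibitor gene Wif1 stood at 33.5 ± 11.9 against 93.2 ± 26.4 TPM (adjusted p = 0.063, with 0.0467 under a filter of 1 TPM in 6 libraries and 0.0458 without healthy replicate 3) and the BMP target gene Id1 at 223 ± 42.9 against 433 ± 48.2 TPM (adjusted p = 0.0986).

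Camera called lists of nerve, ribosomal and basal epithelial genes lower at implants than at teeth, and fry called none of the 3 (adjusted p = 0.204, 0.185 and 0.384). Of 11 Schwann cell and nerve genes 0 were called by limma and 3 were lower adjusted over the list alone, with a median of -1.05 (camera adjusted p = 0.000147, and adjusted p = 0.36 with an estimated correlation). S100b stood at 4.78 ± 1.86 against 12.4 ± 2.92 TPM (adjusted p = 0.109). Of 20 cytosolic ribosomal protein genes 0 were called and 0 adjusted over the list alone, with a median of -0.39 (adjusted p = 9.03e-09, and adjusted p = 0.385 with an estimated correlation), as for Rpl10a (-0.52 ± 0.19, adjusted p = 0.335). Around teeth against healthy tissue 3 of the 20 rose (3 adjusted over the list alone). Fry did not call the list there (adjusted p = 0.0812). Camera called it higher (adjusted p = 0.000465, and adjusted p = 0.594 with an estimated correlation). That call was lost with healthy replicate 1 as the only healthy library (0.0927). Of 15 basal and wound-edge epithelial genes 0 were called and 0 adjusted over the list alone, with a median of -0.29 (adjusted p = 0.0156, and adjusted p = 0.454 with an estimated correlation). This list lost its call without periodontitis replicate 3 (0.0999). Of 17 genes of keratinised epithelium 0 were called and 0 adjusted over the list alone, and the list was not called (adjusted p = 0.0551). The keratin gene Krt76 of the hard palate and gum surface stood at 944 ± 372 against 2753 ± 482 TPM (adjusted p = 0.194, and 0.0496 without healthy replicate 3).

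Skeletal muscle transcripts varied between libraries of a group. Their summed level was 3170, 31.3 and 714 TPM in the healthy libraries, 504, 41.6 and 1153 TPM in the peri-implantitis libraries and 20.5 to 34.4 TPM around teeth. Camera called the list higher at implants than at teeth (adjusted p = 5.3e-05, and adjusted p = 0.46 with an estimated correlation), and fry did not call it (adjusted p = 0.326). Limma called 0 of 15 genes, and 0 adjusted over the list alone, as for Acta1 (4.4 ± 1.88, adjusted p = 0.439).

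Gm25184 (chromosome 2, 181512550 to 181512712), annotated as a small nuclear RNA, was listed at 9.24, 12.4 and 12.86 TPM in the peri-implantitis libraries and at 0 in the other 6. Of its 163 bases, 135 are identical to Tpd52l2, so its value is uncertain. Rpl9, the near copy of Gm15516, stood at 2434 ± 569 TPM at implants and 3209 ± 230 TPM at teeth.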
